A study of Mus musculus with 2 samples.

How the data were processed

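RNA was sequenced from immortalized bone marrow-derived macrophages of C57BL/6 mice, a line that grows continuously in culture and keeps many properties of primary macrophages. There were 2 libraries. The first, labelled WT, carries no infection in its labels, and the labels do not say whether it was mock-treated. The second came from WT cells infected with herpes simplex virus 1 (HSV-1) for 6 h. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, which is not stated to keep strand. The labels' descriptions contain the word "combine", and what was combined is not stated.

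The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, with 1 value per gene and library. Bowtie 0.12.2 and the mouse build mm8 are named, per the submitters' processing notes. The counting tool and the gene annotation are not given in the sources used here. Each library holds the same 12052 rows, of which 11469 have an Ensembl mouse gene ID and 583 are assembled loci with no gene name. Gene symbols were taken from GENCODE M21 by Ensembl ID, and 11434 of the 11469 IDs matched. These IDs come from a later annotation than mm8, so no coordinates are given. No symbol had more than 1 row. Reads of near-identical genes, such as the Ifit, Gbp, Schlafen, Ifi200, H2-T and histone families, may have been split or shared by the counting, and so may reads of overlapping or antisense genes, so their single values are uncertain.

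The FPKM values sum to 606025 in the WT library and 592945 in the infected library, and the median over genes with an Ensembl ID was 12.9 and 13.1. Read counts are unknown, so no counting interval can be given. Relative depth was read from 488 rows above 0 and below 1 FPKM in both libraries, where few reads lie behind each value. With 1 read in the infected library worth 1.34 times 1 read in the WT library, 24.2% of the ratios between libraries lay within 0.1% of a ratio of whole numbers up to 6. The median over the values tried from 1 to 1.8 was 1.02%. Within that range the best match had the WT library deeper by about that factor. Values below 1 were not tried, so the search could not have returned a deeper infected library. An exact 0 in these files can be a failed estimate and is given as "listed at 0".

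The difference between libraries was computed as the log2 ratio of (FPKM + 1), infected over WT, which understates the difference of low genes. Every count of genes at least 2-fold or 4-fold higher or lower, and every statement that a gene lay within 2-fold, uses this ratio of (FPKM + 1). A fold printed for a single gene is instead the ratio of FPKM with nothing added, given only where both libraries were at 1 FPKM or more, so a low gene can exceed 2 on that scale and not be counted. Genes with an Ensembl ID at 1 FPKM or more in at least 1 library entered, 11048 in all. With 1 library per group there is no replicate check, so no p-value is given, and differences between the libraries are not tests of the infection. For each of 35 gene lists written before the data were examined, the median log2 ratio was described by its percentile among 10000 random lists of the same size, matched on mean log2 level in 10 bins. Lists with fewer than 3 genes passing the filter received values only. The lists cover interferon responses, cytokines and chemokines, antigen presentation, cell death, stress, metabolism, proliferation, macrophage functions, other cell types and housekeeping genes. Named genes were the 10 highest and 10 lowest log2 ratios among genes at 5 FPKM or more in a library, the 4 members of each list with the largest absolute log2 ratio and the 4 with the highest mean FPKM, a fixed set of 16 genes, and up to 5 genes per direction listed at 0 in 1 library and at 5 FPKM or more in the other. That rule was written before the data were examined, and genes named outside it are marked. Not every gene that the rule selects is reported here.

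The alternatives were a pseudocount of 0.1 or 5 FPKM, no filter or a filter at 5 FPKM, 4 other scalings of the libraries (rescaling to an equal sum, a median ratio of 1, equal upper quartiles, quantile normalization), a 4-fold threshold, and random lists matched in 5 bins or not matched. The main choice of counting only rows with an Ensembl ID, and the alternatives of counting assembled loci too, protein-coding genes only, no gene listed at 0, or a plain ratio of FPKM, were made after the data were examined. The steps were tested on simulated libraries of 8552 genes at 5 FPKM or more, with 200 genes changed by 4-fold: 100% of the changed genes and 0% of the others passed the 2-fold threshold. The simulated noise was low, so this tests the computation and not the precision of the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Viral transcripts were not analysed here.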

Results

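The data are 2 RNA-seq libraries of immortalized mouse bone marrow-derived macrophages, 1 from WT cells with no infection named and 1 from WT cells infected with HSV-1, a DNA virus, for 6 h. The comparison asks which host genes differ in level between the infected and the WT library. Each group holds 1 library, so no difference below has a replicate check. Values are FPKM, and ratios are log2 of (FPKM + 1), infected over WT. Genes are counted as at least 2-fold higher or lower on that (FPKM + 1) scale, and a fold printed for a single gene is the plain ratio of FPKM. The read depth is unknown. Low values matched best with the WT library at about 1.34 times the depth of the infected one, but a deeper infected library was not tried.

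The infected library held far more interferon beta and interferon-stimulated transcripts than the WT library, while most other genes lay close to equal levels. Ifnb1 (ENSMUSG00000048806), which encodes interferon beta, stood at 0.627 FPKM in the WT library and 57.4 in the infected one. Rsad2 (ENSMUSG00000020641), which encodes the antiviral enzyme viperin, stood at 3.77 and 488 FPKM, 129-fold higher. The chemokine gene Cxcl10 (ENSMUSG00000034855) stood at 4.28 and 267 FPKM, 62.5-fold higher. Of 11048 genes, 210 were at least 2-fold higher in the infected library and 99 at least 2-fold lower, and 10739 (97.2%) lay within 2-fold. At 4-fold, 67 genes were higher and 11 lower, and 42 of those 67 belong to the 3 lists of antiviral effectors, inducible GTPases and interferon signalling. None of the 99 lower genes belongs to those 3 lists. The lists hold only 50, 10 and 36 of the 11048 genes, so few of any 99 genes would fall in them. Rows not annotated as protein-coding made up 733 of the 11048 genes, 37 of the 99 lower ones and 40 of the 210 higher ones. The median log2 ratio over all genes was 0.01. FPKM is scaled to each library's own mapped fragments, so these comparisons are relative. A change in RNA amount shared by most host genes would not show here. Across genes, which are not independent replicates, the log2 levels of the libraries correlated with a Pearson r of 0.973 and a Spearman rho of 0.973. The counts depend on how low genes are treated: with a pseudocount of 5 FPKM they were 105 and 27, and with 0.1 FPKM they were 299 and 228. By the plain ratio of FPKM, among genes at 1 FPKM or more in both libraries, they were 178 and 108.

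**Figure D1:**
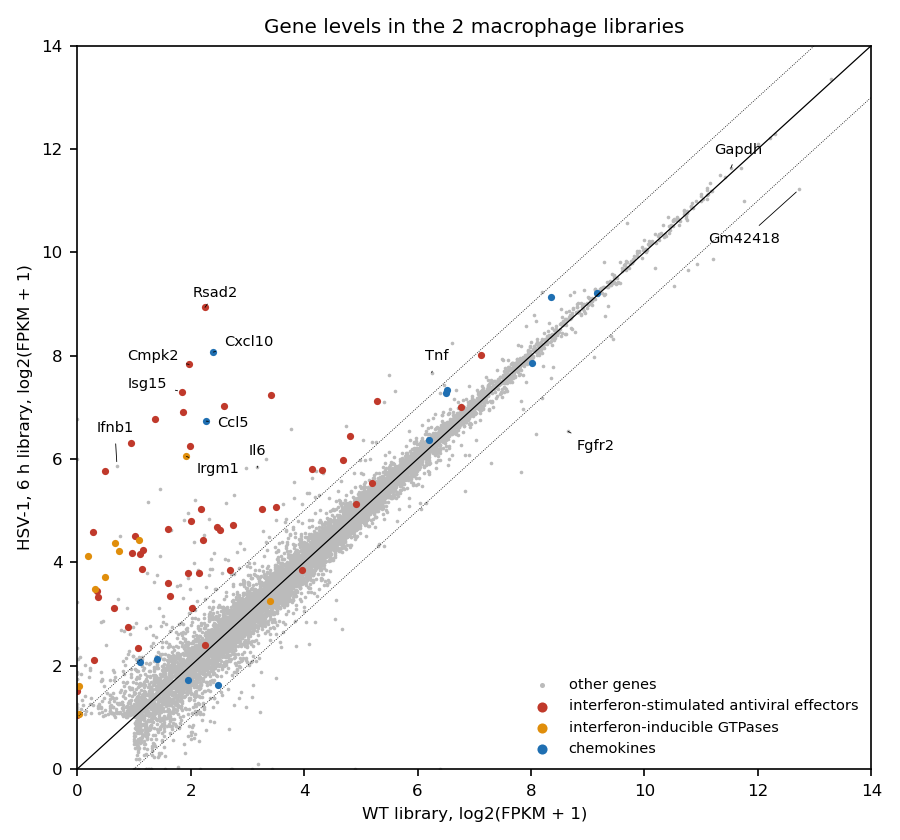
Level of each gene in the WT library (horizontal, log2 of FPKM + 1) and in the library infected for 6 h (vertical, same unit), 1 point per gene, with 3 gene lists in colour, the line of equal levels solid and the 2-fold lines of (FPKM + 1) dotted. Interferon-stimulated effectors lie above the upper dotted line in 44 of 50 cases, whereas Gapdh, at 2939 and 3158 FPKM, lies near the solid line.

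Of 50 interferon-stimulated antiviral effectors that passed the filter, 44 were at least 2-fold higher in the infected library and 0 at least 2-fold lower. Their median log2 ratio was 2.05, above all 10000 random lists (percentile 100), 95% of which lay between -0.06 and 0.07. Cmpk2 (ENSMUSG00000020638), a nucleotide kinase gene, stood at 2.93 and 226 FPKM, 77.3-fold higher. Isg15 (ENSMUSG00000035692), which encodes a ubiquitin-like protein, stood at 2.58 and 157 FPKM, and Ifit1 (ENSMUSG00000034459), which encodes an RNA-binding protein, at 1.58 and 109 FPKM. Ifit3 and Mx2 stood at 0.924 and 0.398 FPKM in the WT library and at 78.6 and 53.2 FPKM in the infected one. Smaller ratios were seen for Bst2 and Ifitm2, both above 100 FPKM in the WT library. Bst2, which encodes tetherin, stood at 137 and 256 FPKM, and Ifitm2 at 108 and 128 FPKM. The list's median was 2.86 with a pseudocount of 0.1 FPKM.

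Interferon-inducible GTPases, which act against intracellular pathogens, were higher in 9 of 10 cases, with a median log2 ratio of 3.29 and a percentile of 100. Irgm1 (ENSMUSG00000046879) stood at 2.80 and 65.2 FPKM, 23.3-fold higher, and Igtp at 1.12 and 20.6 FPKM. Gbp5 and Gbp2 stood at 0.140 and 0.596 FPKM in the WT library and at 16.4 and 19.8 FPKM in the infected one. The remaining member, Gbp8, named after its values were seen, stood at 9.53 and 8.57 FPKM. With pseudocounts of 0.1 and 5 FPKM the median was 4.51 and 1.84.

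Genes of nucleic acid sensing and interferon signalling were uneven. Of 36 genes, 11 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.36 and a percentile of 100. Irf7 (ENSMUSG00000025498), a transcription factor of interferon genes, stood at 1.75 and 42.0 FPKM, and Ddx58, which encodes the RNA sensor RIG-I, at 1.37 and 35.1 FPKM. Ifi204 stood at 0.689 and 21.7 FPKM. The gene of the DNA sensor cGAS, Cgas, stood at 7.17 and 14.9 FPKM, 2.08-fold higher by plain FPKM but with a log2 ratio of 0.96, and was not among the 11. Its downstream partner STING, listed under the symbol Tmem173, stood at 16.9 and 17.5 FPKM, and Irf3, the transcription factor that STING signalling activates, at 24.01 and 23.5 FPKM. Of the type I and III interferons, 5 of 20 genes were measured and 2 passed the filter, Ifnb1 and Ifna4. Ifna4 was listed at 0 in the WT library and at 1.31 FPKM in the infected one.

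Chemokines divided into a few with large ratios and several that were abundant in both libraries. Of 12 genes, 2 were at least 2-fold higher, Cxcl10 and Ccl5, and the median log2 ratio was 0.74, with a percentile of 100. Ccl5 (ENSMUSG00000035042) stood at 3.85 and 105 FPKM, 27.4-fold higher. Ccl2, which attracts monocytes, stood at 326 and 562 FPKM, Ccl3 at 569 and 591 FPKM and Cxcl2, which attracts neutrophils, at 259.5 and 229.8 FPKM. By the plain ratio of FPKM, Ccl12 (1.16 and 3.19 FPKM) and Ccl6 (1.67 and 3.37 FPKM, named after its values were seen) were also more than 2-fold higher, and Ccl20 (4.57 and 2.08 FPKM) was 2.20-fold lower. Among 20 inflammatory cytokines and mediators, 2 were at least 2-fold higher, with a median of 0.32 and a percentile of 100. These were Il6 (ENSMUSG00000025746), at 8.04 and 56.2 FPKM, and Tnf (ENSMUSG00000024401), at 75.1 and 203 FPKM. Il1b, at 1.03 and 2.83 FPKM, was 2.74-fold higher by plain FPKM but not on the (FPKM + 1) scale, and the acute-phase gene Saa3 at 245 and 274 FPKM.

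The NF-kB pathway and feedback genes had a median log2 ratio of 0.23 over 31 genes, with a percentile of 100, and 1 gene at least 2-fold higher. That gene was Tnfaip3, which encodes the inhibitor A20, at 13.2 and 45.7 FPKM. Nfkbie, at 1.08 and 2.75 FPKM, was 2.55-fold higher by plain FPKM alone. Nfkbia, which encodes an inhibitor of NF-kB, stood at 58.9 and 72.4 FPKM. Of 14 negative regulators of cytokine signalling, 5 were at least 2-fold higher: Usp18, Tnfaip3, Socs1, Socs3 and, named after its values were seen, Cd274. Usp18, an ISG15 protease and inhibitor of interferon receptor signalling, stood at 4.98 and 129 FPKM. Socs1 stood at 1.73 and 7.69 FPKM. That list's median was 0.10 (percentile 93.3). Immediate-early genes had a median of 0.06 over 34 genes (percentile 89.3), and 1 was at least 2-fold higher, Ppp1r15a, a stress-response phosphatase subunit gene, at 47.5 and 158 FPKM. Atf3, a stress-induced transcription factor gene, stood at 432 and 599 FPKM.

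Of 23 MHC class I antigen presentation genes, 5 were at least 2-fold higher in the infected library and 0 lower, with a median log2 ratio of 0.47 and a percentile of 100. Tap1, a subunit of the peptide transporter, stood at 3.17 and 14.9 FPKM, H2-T22 at 4.31 and 17.1 FPKM, and B2m, the invariant light chain, at 367 and 478 FPKM. H2-Q4, named after its values were seen, stood at 3.23 and 7.45 FPKM, 2.30-fold higher by plain FPKM, and was not among the 5. MHC class II genes had 3 members passing the filter and a median of 0.19 (percentile 96.2), with Cd74 at 66.8 and 76.7 FPKM. PML body and intrinsic restriction genes were at least 2-fold higher in 7 of 17 cases, with a median of 0.72 and a percentile of 100. Adar, an RNA-editing enzyme gene, stood at 11.3 and 33.9 FPKM, and Sp100, a nuclear body gene, at 2.97 and 10.2 FPKM. Among 14 HSV-1 entry receptors and host cofactors, with a median of 0.16 (percentile 99.6), 1 was at least 2-fold higher, Sdc4, at 15.9 and 39.5 FPKM.

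Inflammasome and lytic cell death genes had a median of 0.27 over 19 genes (percentile 100), with no member beyond 2-fold on the (FPKM + 1) scale, although Il1b exceeded it by plain FPKM. Casp4 stood at 28.5 and 51.8 FPKM, and Pycard, the inflammasome adaptor, at 137 and 132 FPKM. The 24 p53 targets and apoptosis genes had a median of 0.11 (percentile 99.3), with no member beyond 2-fold on either scale.

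The lists with the lowest percentiles were small in size of difference. Cholesterol synthesis and uptake genes had a median log2 ratio of -0.13 over 20 genes (percentile 0.25), with Insig1 at 37.7 and 28.3 FPKM. Cholesterol efflux and liver X receptor targets had a median of -0.17 over 11 genes (percentile 0.27). Among them Apoe (ENSMUSG00000002985), at 4.35 and 1.58 FPKM, was the sole member of any list at least 2-fold lower on the (FPKM + 1) scale. By plain FPKM, Ccl20 and S100a8 were too. Abca1, a cholesterol exporter gene of the same list, was the higher in the infected library, at 24.5 and 32.5 FPKM. The unfolded protein and integrated stress response list had a median of -0.06 over 25 genes (percentile 0.345), with Atf4 at 388 and 341 FPKM and Hspa5 at 232 and 252 FPKM. Proliferation genes had a median of -0.04 over 43 genes (percentile 1.47), with Pcna at 175.0 and 174.7 FPKM. Replication-dependent histones had a median of -0.19 over 11 genes (percentile 3.33). Of the 44 genes in that list 12 were measured, and 7 were at 1 FPKM or more in both libraries. With a filter at 5 FPKM the histone median was -0.016, so the lower value rests on low genes.

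Heat shock genes had a median of -0.0011 over 14 genes (percentile 28.9), and nuclear-encoded respiratory chain genes 0.01 over 55 genes (percentile 8.85). The sign of both medians changed among the 4 other scalings. Cytosolic ribosomal protein genes had a median of 0.04 over 79 genes (percentile 60.3), and housekeeping genes 0.07 over 16 genes (percentile 85.8), with Actb at 822 and 899 FPKM. Glycolysis genes had a median of 0.10 over 20 genes (percentile 98.9). Lysosome and phagocytosis genes had a median of 0.13 over 27 genes (percentile 99.97), with the Fc receptor gene Fcgr1 at 11.6 and 26.4 FPKM. Macrophage identity genes had a median of 0.11 over 20 genes (percentile 98.4), and 2 were at least 2-fold higher, Fcgr1 and Maf. Maf, a transcription factor gene, stood at 5.76 and 12.8 FPKM, C1qb at 1.81 and 4.52 FPKM (2.51-fold higher by plain FPKM alone), C1qc at 1.29 and 0.654 FPKM, Lyz2 at 1390 and 1433 FPKM and Cd68 at 478 and 513 FPKM. Alternative activation genes had a median of 0.16 over 6 genes (percentile 91.8).

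Few markers of other cell types were measured, and most of those were low or shared with macrophages. Measured were 1 of 14 fibroblast, 4 of 15 neutrophil and 2 of 18 lymphocyte genes. Of the dendritic cell list 4 of 13 were measured, and of the erythroid and megakaryocyte list 1 of 13. The levels of the other markers are unknown. Of the epithelial list 0 genes were measured, and of the interferon gamma and lymphoid cytokine list 0 passed the filter. The fibroblast gene Mmp2 stood at 1.75 and 1.52 FPKM, the lymphocyte genes Lck and Cd79b at 2.10 and 1.02 FPKM in the WT library and 2.31 and 1.77 in the infected one, and the megakaryocyte gene Pf4 at 3.47 and 4.11 FPKM. The 3 neutrophil genes had a median log2 ratio of -0.05 (percentile 44.7), with S100a8 at 5.78 and 2.66 FPKM, 2.17-fold lower by plain FPKM. The 3 dendritic cell genes had a median of 0.68 (percentile 99.9), which is the ratio of Tcf4, at 4.69 and 8.09 FPKM. Bst2, also one of the antiviral effectors, had a ratio of 0.89, and Batf3 stood at 16.4 and 13.6 FPKM.

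**Figure D2:**
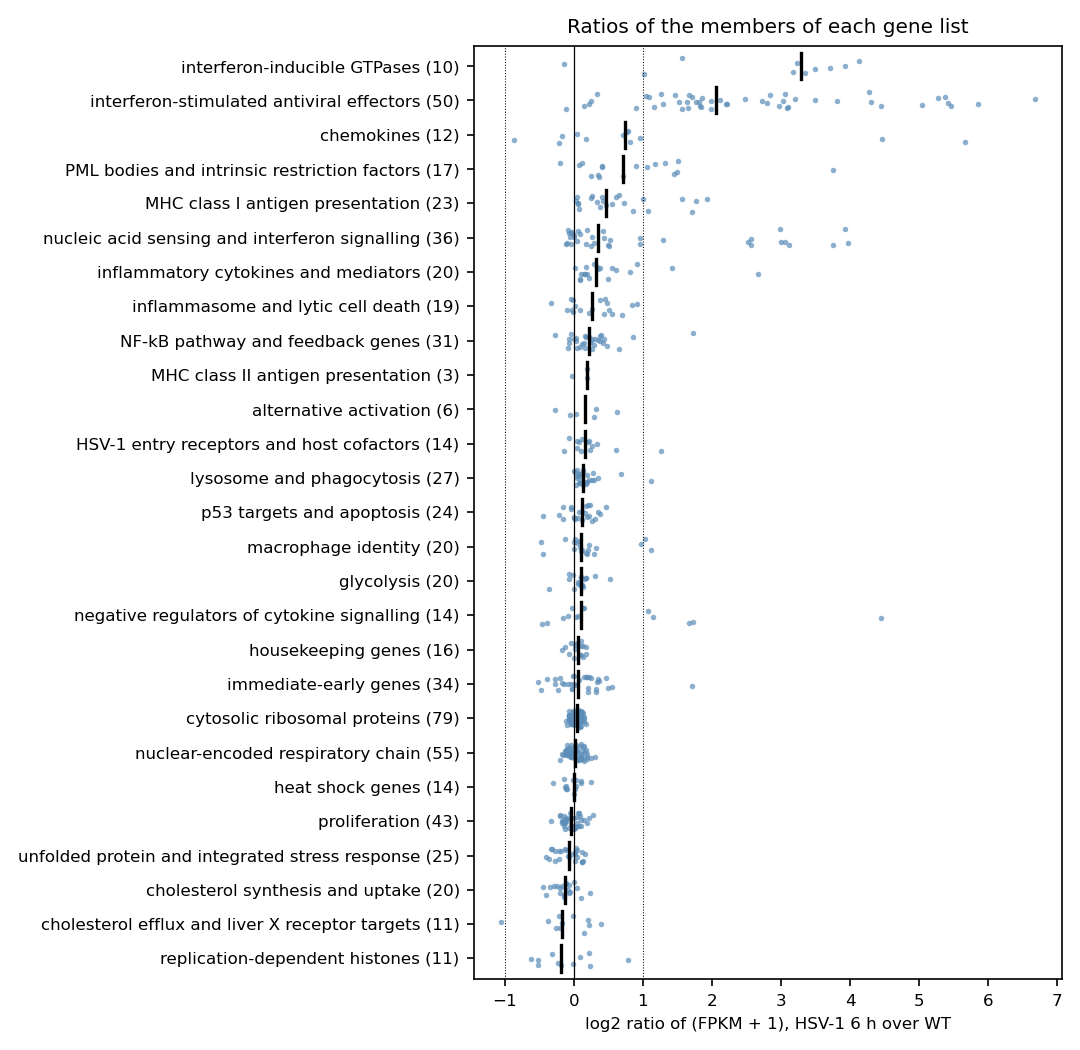
Log2 ratios of (FPKM + 1), infected over WT, of the members of each gene list, 1 point per gene at a random height within its row, with the list's median as a black bar, the number of genes in brackets and dotted lines at 2-fold. Inducible GTPases and antiviral effectors have medians of 3.29 and 2.05, and ribosomal protein genes gather around 0.04.

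Genes lower in the infected library were ranked among those with a symbol and at 5 FPKM or more in a library. There, the lowest log2 ratios with values above 0 in both were those of Slc22a29 (8.12 and 0.0670 FPKM), Ica1l (8.33 and 1.14 FPKM), Fgfr2 (402 and 91.6 FPKM) and Msantd3 (226 and 52.99 FPKM). Fgfr2, a fibroblast growth factor receptor gene, was 4.39-fold lower and Msantd3 4.26-fold lower. Both were among 20 abundant rows at least 2-fold lower, which include a ribosomal RNA locus. Whether these rows hold ribosomal RNA sequence in their introns was not analysed here. The values of Fgfr2 and Msantd3 are therefore those of the rows and not surely of their messenger RNA. A further 9 genes were listed at 0 in 1 library and at 5 FPKM or more in the other. Pknox2 and Osgin2 were listed at 0 in the WT library and at 108 and 63.4 FPKM in the infected one, and Gm3608 at 0 and 8.35 FPKM. In the other direction, Gm10180 and Amhr2 stood at 83.5 and 28.8 FPKM in the WT library, Crip1 at 9.78, Cavin1 at 7.44, Gm7592 at 5.595 and Gm9892 at 5.57, and all 6 were listed at 0 in the infected one. A listed 0 can be a failed estimate, so these genes are given without a fold.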

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

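The tests in this part were chosen after the results were seen. Assembled loci without a gene name are outside the comparison of genes, and 2 of them stood far higher in the infected library. XLOC_008303 was listed at 78.8 FPKM in the WT library and 694 FPKM in the infected one, 8.80-fold higher. XLOC_007527 was listed at 0.418 and 5.62 FPKM. The files name neither gene nor position for these loci. Of 364 assembled loci at 1 FPKM or more in a library, 20 were at least 2-fold higher and 49 at least 2-fold lower.

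The interferon-stimulated antiviral effectors were higher in the infected library by a median log2 ratio of 2.05. A scaling factor common to all genes would shift them all about alike, so it could not set the effectors apart from other genes. That follows from its definition and not from a test here. The median over all genes was 0.01. The effectors' median was at least 2.01 under the 4 other scalings. Those scalings put the median over all genes between -0.029 and 0.040, so they could not have lowered the effectors' median far. None of them tests a change in RNA amount shared by most genes. A general stress response of the infected culture that raises most stress genes is argued against as the whole cause. The highest median among the heat shock, immediate-early and unfolded protein lists was 0.0597. A stress response carried by fewer genes would not move these medians and is not excluded. Ppp1r15a, of the immediate-early list, stood at 47.5 and 158 FPKM. Another difference between the 2 cultures, in handling or batch, cannot be told apart from the infection with 1 library per group. The infection remains open as the biological explanation, untested.

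Of 952 rows with a mean of 100 FPKM or more, 20 were at least 2-fold lower and 11 at least 2-fold higher in the infected library, and the 20 took 7.95% of the FPKM sum in the WT library and 2.78% in the infected one. Among the 20 were the assembled locus XLOC_006828, the most abundant (18131.7 and 4531 FPKM), Gm42418 (6797 and 2382 FPKM), the ribosomal RNA locus CT010467.1 (2369 and 939 FPKM) and the protein-coding genes Fgfr2, Cmss1 and Gphn, singled out after their values were seen, whose introns were not searched here for ribosomal RNA sequence. Of 76 abundant rows that are not protein-coding genes 12 were lower, against 8 of 876 protein-coding ones, but 6 of the 76 were higher. Of those 12, 7 are assembled loci of unknown type, so the 76 are not surely all non-messenger RNA. More non-messenger RNA of every kind in the WT library stays open: the medians of these sets differed by -0.0582, within the spread of the 76, whose middle 50% lay between -0.56 and 0.18. A larger share of ribosomal RNA in the WT library may account for part of it. CT010467.1, at a log2 ratio of -1.33, was the sole row annotated as ribosomal RNA, which is too few to decide. Whether other rows hold such sequence was not examined, and the infection stays open too.

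The 9 genes listed at 0 in 1 library and at 5 FPKM or more in the other may be estimates that failed in 1 library. Such genes occurred in both directions, 3 with the 0 in the WT library and 6 with it in the infected one, as failed estimates would give. The direction alone does not exclude a real difference in any single gene, and an effect of the infection stays open for each.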

How the results depend on the processing

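Alternatives that count assembled loci, protein-coding genes only, no gene listed at 0 or a plain ratio of FPKM were chosen after the data were examined. No paired analysis was possible because each group holds 1 library. The alternative for symbols with several rows was not run, since no symbol had more than 1. With no replicates, a log2 value is called moved when it shifted by more than 1.5-fold, a percentile when it shifted by 5 points and a count when it differed by more than 1.5 times. Under the 4 other scalings no count, and none of the 29 list medians, moved by that much. That limit is wider than most of the list medians themselves, so it cannot show that the small ones are stable. The medians of the heat shock and respiratory chain genes changed sign. The share of higher genes among all beyond 2-fold, 68.0%, ranged from 63.7 to 68.1% under the 4 other scalings. Over the remaining alternatives it ranged from 56.7% with a pseudocount of 0.1 FPKM to 85.9% at 4-fold. The 63.7% came from rescaling to an equal sum, which gave 254 higher and 145 lower genes. That setting raised the values of both libraries while the pseudocount stayed at 1, so it acts partly as a smaller pseudocount. At 4-fold, 67 genes were higher and 11 lower. With a pseudocount of 5 FPKM, 105 were higher and 27 lower, and the median of the inducible GTPases was 1.84. With 0.1 FPKM, 299 genes were higher and 228 lower, and the medians of the antiviral effectors and the GTPases were 2.86 and 4.51. A filter at 5 FPKM left 46 lower genes and a median of -0.89 for the neutrophil markers, and it tests fewer genes. Protein-coding genes alone gave 62 lower genes among 10315. The 733 genes left out there held 37 of the 99 lower ones, so the lower set holds many rows that are not protein-coding. Random lists not matched on level gave percentiles of 90.9 for MHC class II, 6.06 for the unfolded protein list, 42.3 for heat shock genes, 56.9 for the respiratory chain, 91.0 for ribosomal proteins and 32.0 for neutrophil markers. Matching in 5 bins gave 14.8 for the respiratory chain and 70.7 for ribosomal proteins. The cause was not tested. Of 1326 values of named genes under alternatives, 70 moved and 0 changed sign beyond 2-fold. Low genes scatter more: the central 90% of log2 ratios spanned -0.80 to 0.78 at a mean of 1 to 3 FPKM and -0.20 to 0.28 at 100 FPKM or more.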

Other observations

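The families in this part, and the genes named from them, were chosen after their values were seen, and no test was run on them. All 6 Schlafen genes that passed the filter were at least 2-fold higher in the infected library, with Slfn2 at 41.3 FPKM in the WT library and 137 in the infected one and Slfn5 at 2.04 and 23.9 FPKM. Of 7 PYHIN genes of the Ifi200 family, which encode DNA-binding proteins, 6 were at least 2-fold higher. Ifi207 stood at 12.6 and 94.9 FPKM and Mndal at 3.16 and 20.1 FPKM, whereas Aim2, the remaining member, stood at 46.2 and 49.2 FPKM. These genes have close relatives, and how reads shared among them were counted is not given in the sources used here.

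TRIM genes divided. Of 36 that passed the filter, 8 were at least 2-fold higher on the (FPKM + 1) scale and 0 lower, Trim56 (6.97 and 14.2 FPKM) was 2.03-fold higher by plain FPKM alone, and the median log2 ratio was -0.06. Trim21, a cytosolic antibody receptor gene, stood at 1.24 and 18.0 FPKM, and Trim25, which encodes a ubiquitin ligase, at 27.0 and 86.7 FPKM. Of 14 PARP genes, 4 were at least 2-fold higher, Parp14, Parp10, Parp12 and Parp9, and Parp14 stood at 1.02 and 21.7 FPKM. Of 8 interferon regulatory factor genes, 3 were at least 2-fold higher, Irf7, Irf9 and Irf1, with Irf1 at 5.14 and 34.4 FPKM. Among 8 toll-like receptor genes 1 was at least 2-fold higher, Tlr3, at 0.744 and 3.28 FPKM, and among 8 caspase genes 0 were.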
